A study of Zea mays with 15 samples.

How the data were processed

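RNA-seq was measured in 12 libraries of maize leaf, 3 for each of 4 groups made by genotype (Y331-ΔTE or Y331 with the TE insertion) and treatment (normal or drought), with leaves of 3 seedlings pooled per library. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was bound to poly-T beads and cDNA was primed with random hexamers, and the strand setting is not given in the sources used here. Of the 15 samples of the series, the 3 DAP-seq samples are not analysed here.

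Each deposited file is a table per RefSeq transcript with estimated counts (expected counts), TPM, length and effective length, per the file headers. Per the submitters' processing notes, the tools were Trim Galore, Salmon 1.10.2, DESeq2, Bowtie2 2.5.1 and deepTools 3.5.1, and no role, genome build, annotation release or option is given in the sources used here. The deposited estimated counts were not scaled between samples, as their column sums differ, and the deposited TPM sum to the same total in every sample. Reads from near-identical paralogs or from overlapping or antisense genes may be divided between them in such counts, so levels within families carry that uncertainty.

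Estimated counts of 74405 transcripts were summed per gene through a reference table of assembly Zm-B73-REFERENCE-NAM-5.0, used for gene names, chromosome and gene order and for no coordinates, since the build behind the files is not given. Of the transcripts, 71257 matched with their version, 1965 without it, and 1183 did not match and were kept as their own features (1.35 to 1.69% of counts per library). This gave 43152 features, 41969 of them matched genes. Sums were rounded to whole counts. Library totals ran from 16592762 to 21724724 counts, so that a floor of 3 counts was 0.138 to 0.181 CPM. Ratios against a group with 1 to 3 counts carry 95% counting intervals, and folds against a group with 0 counts are lower bounds at 3 counts over the group.

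The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust, TMM scaling) in 1 model of all 12 libraries with a mean per group, after edgeR's filterByExpr (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment over 24796 genes and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The contrasts were TE insertion against ΔTE under normal water and under drought, drought against normal in each genotype, and the difference of the drought responses. The common biological coefficient of variation was 0.263.

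Gene lists were fixed as symbol patterns before the data were examined, and symbols or synonyms decided membership, since the reference table gives no descriptions for the description patterns. By symbol, 6 of the 19 tested pathogenesis-related and chitinase members fit the name of their list, 2 of 12 LEA and dehydrin, 1 of 5 proline, 1 of 4 raffinose and trehalose, 15 of 17 photosystem, 20 of 23 cell cycle, 18 of 20 clock and flowering, 8 of 9 root, 17 of 18 auxin response, 4 of 5 chlorophyll breakdown and 5 of 6 C4 mesophyll members. They were tested with camera (limma 3.58.1) at a correlation of 0.01 on log2 CPM with prior count 2, adjusted over the lists of a contrast. Lists with fewer than 5 tested members were described by their members. Counts of called members come from edgeR, adjusted over all genes and over the list alone. Named genes followed a rule fixed at the same time. In each contrast it took the 8 genes that rose and the 8 that fell most among calls with a mean of at least 5 CPM, no overlap between groups and a symbol that is more than a locus number, and up to 3 called members with the smallest adjusted p per list, or the most abundant member of a list with no call.

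Chromosome 10 was compared with the rest by Fisher's exact test. The planned windows by length were replaced by stretches of consecutive tested genes, since no coordinates were used. The densest stretch of 150 tested genes was set against 10000 random placements of the calls. Genes that part the genotypes were defined in the normal water libraries by a gap of 2 in log2(CPM + 0.5) between the nearest libraries of the groups, and each drought library was placed by the nearer group mean. Correlations of fold changes run across genes.

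Alternatives were DESeq2 1.42.0 (its own test and its size factors in edgeR), limma-voom, upper-quartile scaling, no filter, a filter of 1 CPM in 3 samples, only the 2 groups compared, a replicate block, a fold threshold, length-scaled TPM, other list tests and leaving out each library. Lists without members whose symbol means another gene, and fits without libraries that stood apart, were added after seeing the data.

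The gene and list tests were tested on simulated data drawn from the real libraries' means and depths. For 1.5-, 2- and 4-fold changes, the test recovered 17.9, 38.8 and 71.2% of changed genes for TE insertion under normal water (24239 genes), 6.0, 44.8 and 74.2% for drought in ΔTE (24220 genes) and 1.5, 34.3 and 71.2% for the interaction (24235 genes). False calls were 9 of 94, 5 of 88 and 6 of 77 calls (9.6, 5.7 and 7.8%), above the nominal 5%. No simulated library was placed against its label, so the shares recovered may not hold for the real libraries. Of the 33 real genes that part the genotypes in normal water, 0 were called there with all libraries. For lists, camera called a shifted list of 15 genes and did not call an unchanged one of 15 (24796 genes). A single list of each kind gives no rate of false list calls. Lists with correlated members were not tested in this way. Among the real lists, the estimated correlation was 0.662 for photosystem and 0.436 for benzoxazinoid genes. The simulation therefore cannot say how often camera with its preset correlation calls such lists falsely.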

Results

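Leaf RNA of maize seedlings was sequenced from a pair of related lines, each sampled before and after drought stress. Per the labels, Y331 carries a transposable element (TE) insertion that makes ZmCCT non-functional, and Y331-ΔTE, the control, carries wild-type ZmCCT. ZmCCT is a CCT-domain regulator known for its role in flowering time. Leaves of 3 seedlings at the 3-leaf stage were pooled per library, with 3 libraries for each of 4 groups: ΔTE normal, TE insertion normal, ΔTE drought and TE insertion drought. The labels speak of plants before or after stress, so harvest time goes with water supply and the drought comparisons cover both. Total estimated counts of replicates 1 to 3 were 18129068, 16865581 and 16592762 for ΔTE normal, 17531570, 17666222 and 17170567 for TE insertion normal, 18627087, 18185194 and 21724724 for ΔTE drought and 19272893, 18744626 and 18628405 for TE insertion drought. Intervals and floors below cover counting error only. The DAP-seq libraries of the series (2 IP, 1 input) are not analysed here.

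The names fixed for ZmCCT before the data were examined match no gene in the reference table, so its level is not reported here and does not check the genotype labels. Spearman correlations within groups ran from 0.967 to 0.983. The first principal component (34.9% of the variance) parted normal from drought libraries. On the second component (10.2%), 2 ΔTE libraries lay apart from the rest, normal replicate 2 at 48.4 and drought replicate 2 at 73.2. On the same component the library labelled TE insertion drought replicate 2 lay at -5.7, against -43.8 and -43.1 for the other two of its group. Gene levels below are TMM-scaled CPM ± SD, and log2 fold changes are ± SE, both with n = 3 per group.

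Under normal water, the comparison of TE insertion with ΔTE asks which genes differ between the lines before stress. Loss of functional ZmCCT and any other difference between the lines cannot be told apart in it. Of 24796 genes tested, 29 differed between the lines, 8 higher and 21 lower in TE insertion (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). CK1 was the single gene with a descriptive symbol that met the naming rule. It fell from 103 ± 13.8 CPM in ΔTE to 50.5 ± 8.10 CPM in TE insertion (log2 fold change -1.02 ± 0.14, edgeR adjusted p = 0.00703). The other calls carry locus numbers as names, and those given here were chosen after their values were seen. LOC103649654 rose from 10.8 ± 1.62 to 49.4 ± 3.50 CPM (log2 fold change 2.19 ± 0.24, edgeR adjusted p = 0.00422) and LOC103647908 from 17.7 ± 3.10 to 52.7 ± 3.33 CPM. LOC100281947 fell from 19.5 ± 1.85 to 2.50 ± 1.99 CPM (log2 fold change -2.96 ± 0.50) and LOC100275437 from 14.4 ± 4.11 to 2.85 ± 1.34 CPM.

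Of the gene lists fixed before the data were examined, jasmonate synthesis and signalling was the one that passed, towards lower values in TE insertion (camera adjusted p = 9.59e-05). None of its 42 measured members was called over all genes and 1 was lower adjusted over the list alone. That list call was lost in the alternative test, with adjusted p = 0.774 with an estimated correlation, and other splits of the 6 libraries gave up to 6 passing lists. No member of any other list was called over all genes. Adjusted over the list alone, 2 pathogenesis-related and chitinase members (pr6 and the peroxidase PRX42), 1 cell wall loosening and cellulose member and 1 ABA synthesis and breakdown member were lower. Benzoxazinoid synthesis had a median of -0.25 with a mean of 0.0. Median and mean also took opposite signs for the lists of cytosolic ribosomal proteins, aquaporins, raffinose and trehalose genes and ARF, GH3 and SAUR genes, and the test of reactive oxygen enzymes pointed down over a median of 0.01.

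Some of the called genes gathered on chromosome 3, which held 9 of the 28 placed calls. Of the 28 calls placed on a chromosome, 8 lay within a stretch of 150 consecutive tested genes there, against a highest count of 5 in 10000 random placements of the calls (one-sided permutation p = 1e-04, the smallest these placements can give). In this stretch LOC103649654, LOC103649623 and LOC103651743 were higher in TE insertion, and LOC100275594, LOC100277712, LOC100283536, LOC100285293 and LOC110973014 were lower. All 8 were chosen after their values were seen. Chromosome 10, where ZmCCT lies, held 1 of the 28 calls (3.57%, against 6.46% of tested genes; Fisher's exact test, two-sided p = 1). The chromosome 10 share ran from 0% (0 of 1 placed call) to 16.7% (1 of 6) when single libraries were left out. Without the library labelled TE insertion drought replicate 2, it was 4 of 128 (3.12%; Fisher's exact test, two-sided p = 0.148).

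**Figure D1:**
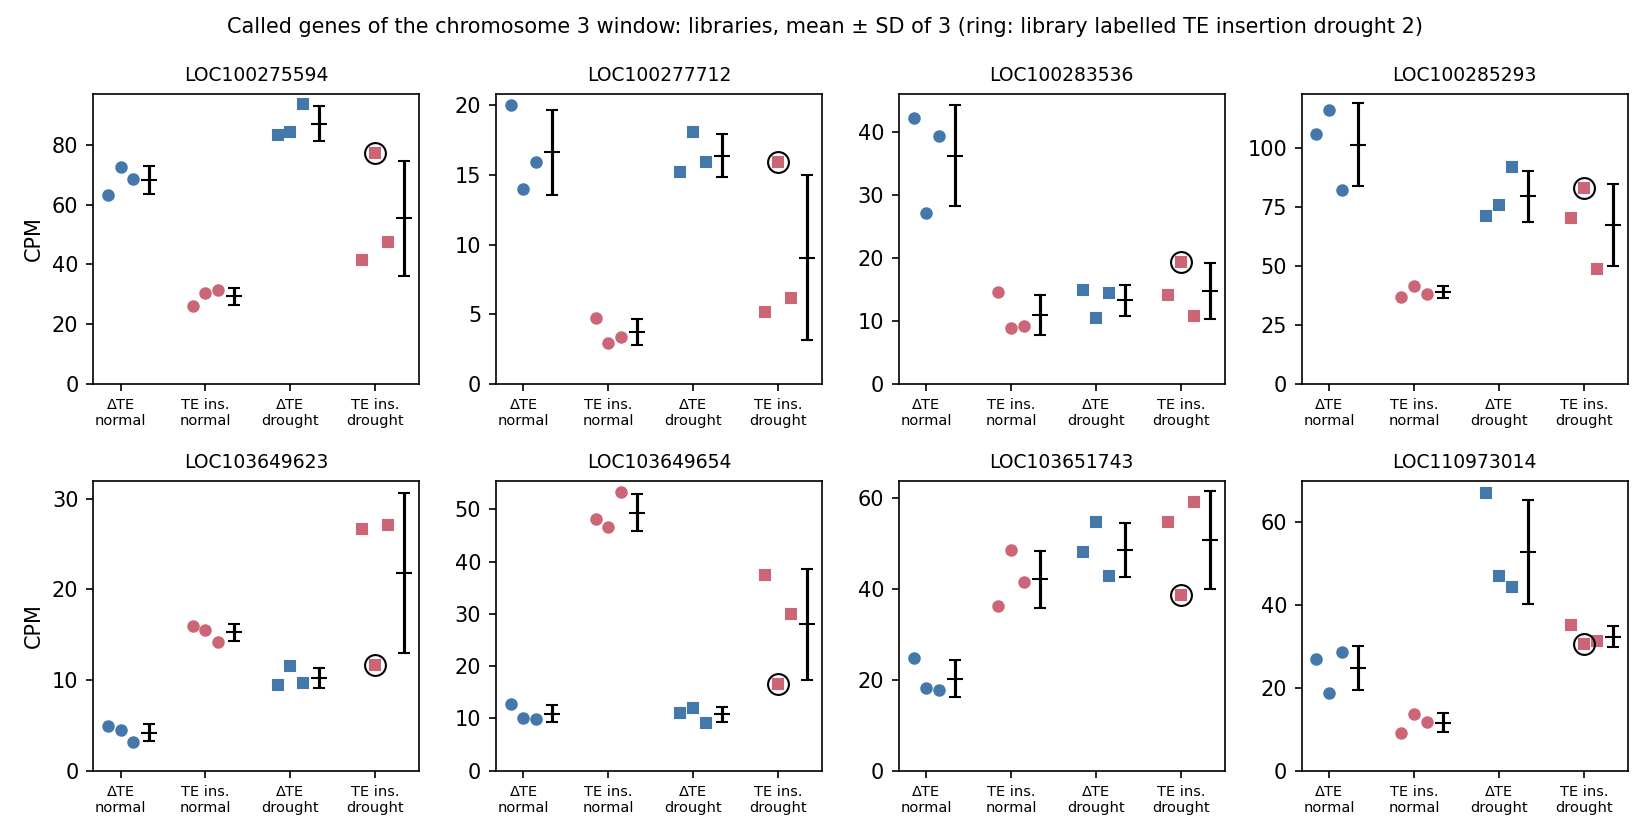
Levels in CPM of the 8 called genes of the chromosome 3 stretch, 1 panel per gene, with 1 point per library in the 4 groups and bars for mean ± SD of 3. The ringed point is the library labelled TE insertion drought replicate 2, which for LOC103649654 lies at 16.5 CPM against 37.5 and 30.0 CPM in the other two of its group.

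The count of 29 moved to 199 with DESeq2, 120 with only the 2 groups in the fit, 62 with no filter, and to 6, 17, 10, 13, 2 and 18 without ΔTE normal replicate 1, 2 or 3, TE insertion normal replicate 1 or 3, or ΔTE drought replicate 1. It rose to 133 (39 up, 94 down, with all 29 kept) without the library labelled TE insertion drought replicate 2, and in all libraries 11.2% of genes had non-overlapping groups, where chance gives 10%.

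Under drought, the same comparison asks which genes differ with the genotype after stress. A single gene, LOC100284402, passed and was higher in TE insertion, at 25.1 ± 4.71 CPM against 6.06 ± 1.47 CPM in ΔTE (log2 fold change 2.05 ± 0.27, edgeR adjusted p = 0.0304). It was chosen after its values were seen. No list passed camera, the smallest adjusted p being 0.0852 for cytosolic ribosomal proteins. No list member was called over all genes. Adjusted over the list alone, 2 jasmonate members were lower and 1 higher, 2 phenylpropanoid members were lower and gols2 of the raffinose and trehalose list was lower. On that scale 3 cell cycle, 2 HD-ZIP, 2 shoot meristem and 1 root marker members were higher. PAL1, the entry enzyme of phenylpropanoid synthesis, stood at 114 ± 10.3 CPM in TE insertion and 227 ± 50.8 CPM in ΔTE (log2 fold change -0.99 ± 0.17, edgeR adjusted p = 0.0569). Median and mean differed in sign for the shoot meristem, NAC, C4 mesophyll, WRKY and ABA synthesis lists, the glutathione transferase test pointed up over a negative median and mean, and benzoxazinoid synthesis had a median of -0.05 with a mean of 0.0.

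One library of this comparison stood apart from its label. In normal water 33 genes parted the genotypes by at least 2 log2 units between the nearest libraries, 14 higher and 19 lower in TE insertion, a gap chosen after the data were seen. The other splits of the 6 normal libraries gave at most 9 such genes. The ΔTE drought libraries lay nearer the ΔTE mean at 32, 31 and 32 of these genes. The libraries labelled TE insertion drought replicates 1 and 3 did so at 1 and 2 genes, and the library labelled TE insertion drought replicate 2 at 32, among them all 14 higher and 18 of the 19 lower genes. The 27 of these genes with a chromosome lay on 8 chromosomes, with 0 on chromosome 10, where ZmCCT lies. Of the 33 genes, 0 were among the 29 normal water calls with all libraries. Without the library labelled TE insertion drought replicate 2, 31 of them were among the 133 normal water calls. LOC103638482, chosen after its values were seen, was at 49.7 and 50.5 CPM in replicates 1 and 3 and at 0 in replicate 2, as in the ΔTE libraries of both conditions.

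**Figure D2:**
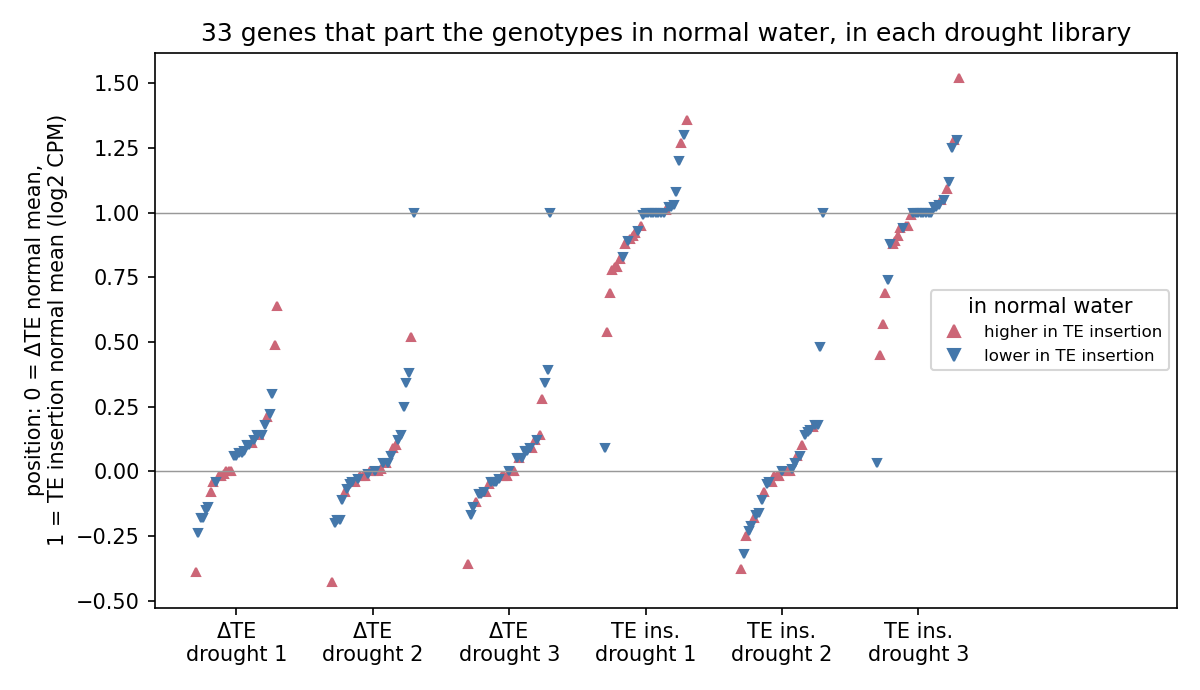
Position of each of 33 genes in each drought library on a log2 CPM scale where 0 is the ΔTE normal mean and 1 the TE insertion normal mean, 1 point per gene. The library labelled TE insertion drought replicate 2 lies near 0 with the ΔTE libraries, nearer ΔTE at 32 genes, and the other TE insertion libraries lie near 1.

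Without that library 102 genes differed under drought (44 up, 58 down, with LOC100284402 among them), and 26 of them rose and 41 fell in normal water too, where independent lists would share 0.0675 and 0.215. With all libraries the count was 1 by edgeR (1771 genes at an unadjusted p under 0.05), 119 by DESeq2, 7 by limma-voom, 18 with no filter, 7 with only the 2 groups in the fit and 8 from length-scaled TPM. It was 0 without TE insertion normal replicate 3, ΔTE drought replicate 1 or TE insertion drought replicate 1. Without any other single library bar the one above, it was from 2 to 10. The 5 calls without ΔTE drought replicate 3 did not include LOC100284402. With all libraries, 13.2% of genes had non-overlapping groups, where chance gives 10%.

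In ΔTE, the comparison of drought with normal water asks how the control line responds to stress. Of the list of cell wall loosening and cellulose genes 11 of 16 rose, and of photosystem genes 13 of 17 fell, though the photosystem genes as a list passed with the preset correlation and not otherwise in camera (adjusted p = 0.676 with an estimated correlation). The secondary wall cellulose synthase cesa10 rose from 0.300 ± 0.341 to 37.4 ± 5.15 CPM (128-fold, SE 0.59 on the log2 scale, edgeR adjusted p = 1.55e-05), and bx1, which opens the benzoxazinoid defence pathway, from 725 ± 114 to 2783 ± 75.5 CPM (log2 fold change 1.94 ± 0.24). The chlorophyll a/b binding gene cab-m1 fell from 727 ± 299.8 to 28.9 ± 14.2 CPM (log2 fold change -4.65 ± 0.68). In all 4519 genes changed, 2173 up and 2346 down, and 2143 of them by at least 1 log2 unit.

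Of the list of cell wall loosening and cellulose genes, 11 of 16 measured members rose and 0 fell (11 and 0 adjusted over the list alone), and the list passed (camera adjusted p = 2.06e-06). This call held in the alternative test, with adjusted p = 0.0155 with an estimated correlation. Beside cesa10, the secondary wall subunits CesA12 and cesa11 rose by 7.16 and 6.72 log2 units, the xyloglucan-remodelling gene xth1 by 6.38 and the COBRA-like bk2 by 3.23. Outside the list the laccase Laccase-17 (LOC100281551), of a class that polymerises lignin, had 2 counts in normal water and 1154 under drought, a CPM ratio of 475 (95% counting interval 131 to 3930). The laccase lac4 rose by 6.52 ± 0.67 log2 units, Bk2L7 by 6.40 ± 0.65 and IRL by 6.59 ± 0.38. Of phenylpropanoid and flavonoid genes 2 of 9 measured members rose and 1 fell (3 and 1 adjusted over the list alone), with camera adjusted p = 0.0379 and adjusted p = 0.315 with an estimated correlation. PAL1 rose by 3.04 ± 0.18 and BM1, a lignin-pathway gene, by 1.51 ± 0.18 log2 units, and a2 (LOC606406) fell by 0.34.

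Of photosystem and light harvesting genes 1 of 17 measured members rose and 13 fell (2 and 13 adjusted over the list alone). The list passed towards lower values (camera adjusted p = 0.000409), and the call was lost at adjusted p = 0.676 with an estimated correlation. PSBQ of the oxygen-evolving complex fell by 1.45 log2 units and CAB1 went from 12690.0 ± 3911 to 5263 ± 1497 CPM. The member that rose, psat1, carries a symbol shared with a serine synthesis enzyme, and of the 15 members that fit by symbol 12 fell. Among C4 mesophyll markers, 1 up and 1 down of 6 (1 and 2 adjusted over the list alone), pep4 rose by 0.73 and Ppdk1, of the carbon-concentrating cycle, fell by 0.63. Of the 4 C4 bundle sheath markers, too few for a list test, rca1 (rubisco activase) fell by 0.97 and 3 were not called (1 up and 2 down adjusted over the list alone). Of chlorophyll breakdown genes, 2 up and 0 down of 5 (2 and 0 adjusted over the list alone), the stay-green gene SGR1 rose by 1.64 and PAO, a symbol shared with polyamine oxidase, by 0.83.

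Of benzoxazinoid genes 8 of 11 measured members rose and 0 fell (8 and 0 adjusted over the list alone). The list passed (camera adjusted p = 1.54e-06), and the call was lost at adjusted p = 0.315 with an estimated correlation. Beside bx1, bx6 and BX5 rose by 1.94 and 1.61 log2 units. Lipid transfer, wax and cutin genes also passed (camera adjusted p = 0.0346, but adjusted p = 0.315 with an estimated correlation), with 3 up and 0 down of 7 (3 and 0 adjusted over the list alone). The phospholipid transfer gene plt2 rose by 2.94 and CER1 (LOC100280261), of wax alkane synthesis, by 1.36. Jasmonate genes did not pass (camera adjusted p = 0.113), with 7 up and 3 down of 42 (9 and 3 adjusted over the list alone). There lox6 and aos1 rose by 2.58 and 1.88, and opr6 fell by 1.54.

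Abscisic acid (ABA) perception genes passed towards lower values (camera adjusted p = 0.0229, but adjusted p = 0.315 with an estimated correlation), with 0 up and 5 down of 19 (0 and 7 adjusted over the list alone). The receptors PYL10 (LOC100274679), PYL7 and PYL9 fell by 1.29, 1.21 and 0.91 log2 units. Root markers passed in the same direction (camera adjusted p = 0.0346, but adjusted p = 0.315 with an estimated correlation), with 0 up and 4 down of 9 (0 and 6 adjusted over the list alone), and the phosphate transporters pht3, pht2 and pht1 fell by 2.14, 3.04 and 0.84. Of 4 ABA synthesis genes, aba1 (zeaxanthin epoxidase) rose by 0.52, also adjusted over the list alone. The dehydrin dhn1 went from 0 counts in normal water to 338 under drought, at least 92.7-fold higher against a floor of 3 counts over the group. Its relative dhn2 rose by 3.38 ± 0.55, and these are the 2 of the 12 measured members of the LEA and dehydrin list whose symbols fit its name. The list had 2 up and 0 down of 12 (2 and 0 adjusted over the list alone).

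The remaining lists did not pass, with camera adjusted p from 0.0795 to 0.912 among those with no list call. Pathogenesis-related and chitinase genes had 1 up and 6 down of 19 (2 and 7 adjusted over the list alone), with pr6 at -2.68 ± 0.53. Of its called members, prcw1, PRR59, prf5 and prh1 carry symbols of other kinds of genes. Aquaporins had 3 up and 6 down of 22 (4 and 7 adjusted over the list alone), with PIP1-3 at 1.25 and pip1-2 at -0.82. Glutathione transferases had 4 up and 1 down of 25 (4 and 1 adjusted over the list alone), led by GST25 at 3.51 ± 0.55. WRKY factors had 0 up and 2 down of 18 (0 and 2 adjusted over the list alone), NAC factors 2 up and 3 down of 17 (2 and 4 adjusted over the list alone) and HD-ZIP factors 4 up and 3 down of 20 (5 and 3 adjusted over the list alone). Heat shock proteins had 1 up and 2 down of 14 (1 and 2 adjusted over the list alone), reactive oxygen enzymes 3 up and 2 down of 14 (4 and 3 adjusted over the list alone) and cytosolic ribosomal proteins 2 up and 1 down of 29 (2 and 1 adjusted over the list alone). Ethylene genes had 3 up and 4 down of 27 (3 and 4 adjusted over the list alone), with acs7 of ethylene synthesis at -3.26. Auxin response genes (ARF, GH3 and SAUR) had 1 up and 2 down of 18 (4 and 2 adjusted over the list alone), and the 1 measured Aux/IAA member, BIF1, was at 0.51 and not called. Clock and flowering genes had 2 up and 5 down of 20 (2 and 6 adjusted over the list alone), with the GIGANTEA gene gigz1a at -0.74 and PRR59 at -0.59. The proline list had 1 up and 1 down of 5 (1 and 1 adjusted over the list alone), where p5cr, the 1 member that fits its name by symbol, rose by 0.64 and the member that fell, a pdh2 gene (LOC541705), has a symbol of pyruvate dehydrogenase. Of the 4 measured members of the raffinose and trehalose list gols2, the 1 that fits by symbol, rose by 0.89, also adjusted over the list alone. Shoot meristem markers had 1 up and 0 down of 7 (1 and 1 adjusted over the list alone) and cell cycle genes 2 up and 2 down of 23 (2 and 4 adjusted over the list alone). Median and mean differed in sign for the shoot meristem, circadian, ethylene and cell cycle lists, and for reactive oxygen enzymes the mean was negative under an upward test.

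Among other genes that met the naming rule, the cysteine protease gene vignain fell by 5.45, AGA3a by 3.94, CKX10 (cytokinin oxidase) by 3.48, ciszog1 (zeatin glucosyltransferase) by 3.41 and gln2 by 2.82 log2 units. Of all genes, 32.1% had non-overlapping groups, where chance gives 10%, and other splits of the 6 libraries gave up to 6 passing lists against the 7 here.

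**Figure D3:**
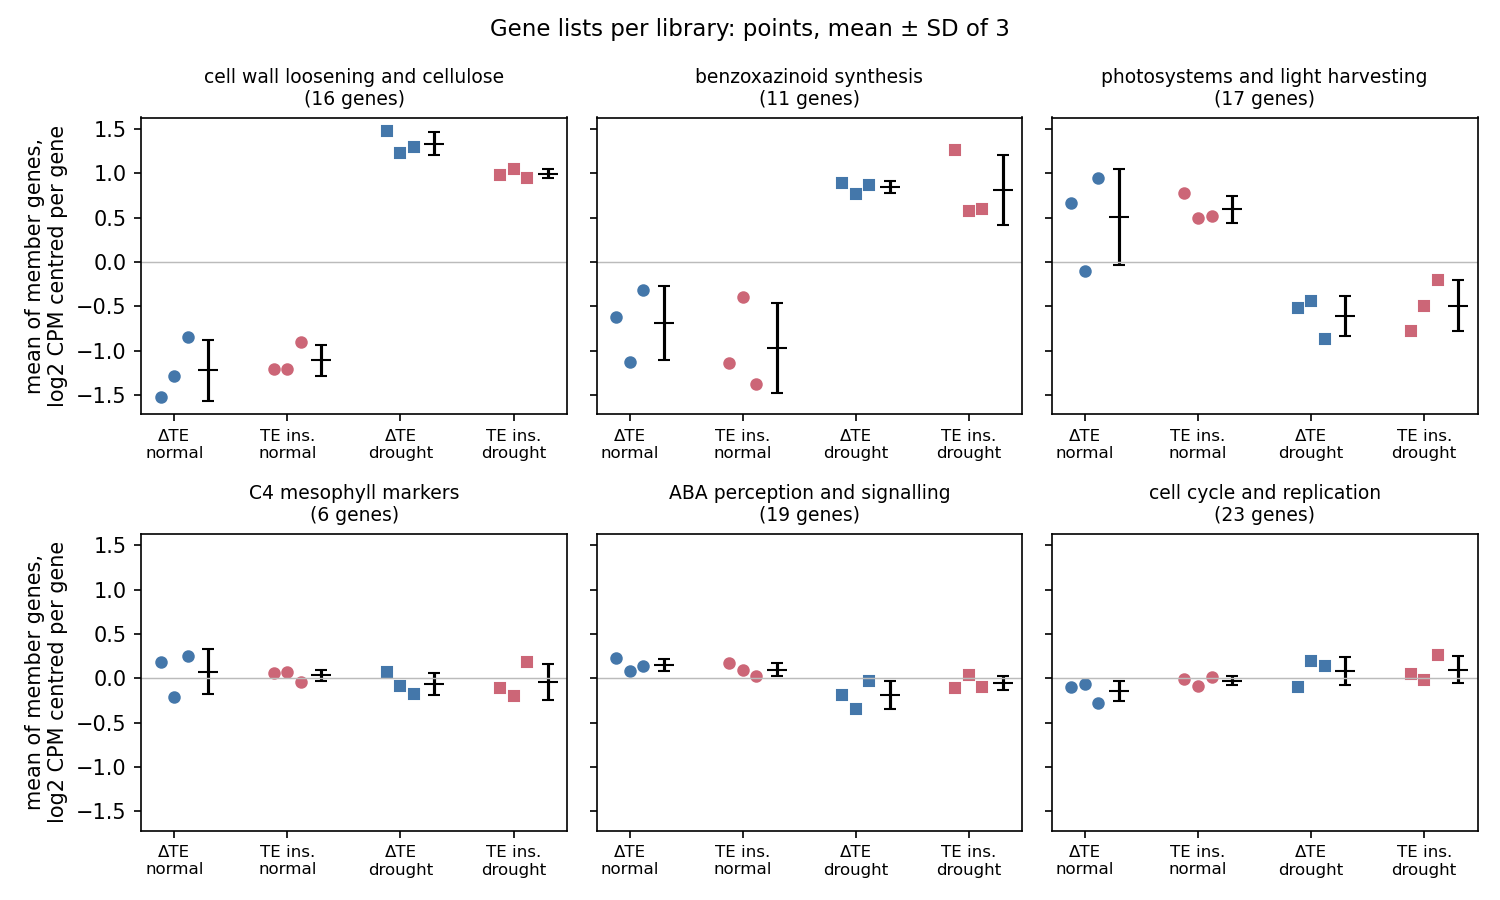
Mean of the member genes of selected lists per library, as log2 CPM centred per gene, with 1 point per library in the 4 groups and bars for mean ± SD of 3. In both genotypes cell wall loosening and cellulose genes lie higher and photosystem genes lower under drought.

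In TE insertion, the comparison of drought with normal water asks for the response in the line without functional ZmCCT, and includes the library labelled TE insertion drought replicate 2. Of the list of cell wall loosening and cellulose genes 11 of 16 rose, and of photosystem genes 12 of 17 fell, though the photosystem genes as a list passed with the preset correlation and not otherwise in camera (adjusted p = 0.508 with an estimated correlation). cesa10 rose from 0.159 ± 0.180 to 21.1 ± 7.58 CPM (128-fold, SE 0.64 on the log2 scale, edgeR adjusted p = 3.34e-05), bx1 from 494 ± 208 to 2818 ± 166 CPM (log2 fold change 2.51 ± 0.24), and cab-m1 fell from 787 ± 229.8 to 76.8 ± 50.5 CPM (log2 fold change -3.36 ± 0.64). In all 3353 genes changed, 1706 up and 1647 down, and 1509 of them by at least 1 log2 unit.

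Of the list of cell wall loosening and cellulose genes, 11 of 16 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 4e-06 and, holding, adjusted p = 0.0181 with an estimated correlation. CesA12 rose by 6.68, cesa11 by 5.39, xth1 by 5.82 and bk2 by 2.82 log2 units. Outside the list Bk2L7 rose by 6.93 ± 0.72, the tubulin tub6 by 5.05 ± 0.55 and the annexin Ann9 by 4.74 ± 0.37. Of photosystem genes 1 of 17 measured members rose and 12 fell (1 and 13 adjusted over the list alone), with camera adjusted p = 8.16e-06, lost at adjusted p = 0.508 with an estimated correlation. There psaN of photosystem I fell by 1.47 and PSBQ by 1.31. Of benzoxazinoid genes 8 of 11 measured members rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 9.34e-08, lost at adjusted p = 0.244 with an estimated correlation. BX5 and BX4 rose by 1.81 and 1.57. Lipid transfer, wax and cutin genes had 5 up and 0 down of 7 (5 and 0 adjusted over the list alone), with camera adjusted p = 0.000728 and adjusted p = 0.244 with an estimated correlation, and plt2 rose by 3.17. Jasmonate genes had 8 up and 2 down of 42 (13 and 2 adjusted over the list alone) and passed (camera adjusted p = 0.00317, but adjusted p = 0.508 with an estimated correlation), with aos1 at 1.82, lox6 at 1.73 and opr6 at -1.25.

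The other lists did not pass, with camera adjusted p from 0.0743 to 0.85. Phenylpropanoid genes had 3 up and 1 down of 9 (4 and 1 adjusted over the list alone), with PAL1 at 2.52 ± 0.18. ABA perception genes had 0 up and 3 down of 19 (0 and 5 adjusted over the list alone), with PYL10 (LOC100274679) at -1.10, and root markers 0 up and 1 down of 9 (0 and 1 adjusted over the list alone), with pht3 at -1.76. HD-ZIP factors had 4 up and 1 down of 20 (4 and 1 adjusted over the list alone), WRKY factors 0 up and 3 down of 18 (0 and 3 adjusted over the list alone) and NAC factors 0 up and 2 down of 17 (0 and 2 adjusted over the list alone). Aquaporins had 3 up and 4 down of 22 (3 and 4 adjusted over the list alone), with PIP1-3 at 1.51. Clock and flowering genes had 1 up and 5 down of 20 (2 and 8 adjusted over the list alone), with COL8 at -0.94, and glutathione transferases 1 up and 0 down of 25 (1 and 0 adjusted over the list alone), with GST25 at 2.86. The LEA and dehydrin list had 0 up and 0 down of 12 (0 and 0 adjusted over the list alone), though only dhn1 and dhn2 fit its name by symbol, heat shock proteins 0 up and 0 down of 14 (0 and 0 adjusted over the list alone) and cytosolic ribosomal proteins 1 up and 0 down of 29 (1 and 0 adjusted over the list alone). Pathogenesis-related and chitinase genes had 2 up and 4 down of 19 (2 and 4 adjusted over the list alone), all 6 called members with symbols of other kinds of genes, ethylene genes 3 up and 1 down of 27 (3 and 1 adjusted over the list alone) and auxin response genes 1 up and 2 down of 18 (1 and 2 adjusted over the list alone). Reactive oxygen enzymes had 2 up and 3 down of 14 (3 and 3 adjusted over the list alone), cell cycle genes 3 up and 1 down of 23 (3 and 2 adjusted over the list alone), among them a cyclotide gene of another kind, and shoot meristem markers 1 up and 1 down of 7 (2 and 1 adjusted over the list alone). Chlorophyll breakdown genes had 2 up and 0 down of 5 (2 and 0 adjusted over the list alone), with SGR1 at 1.31, C4 mesophyll markers 1 up and 0 down of 6 (1 and 1 adjusted over the list alone), with pep4 at 1.03, and the proline list 1 up and 1 down of 5 (1 and 1 adjusted over the list alone), where p5cr, the 1 member that fits by symbol, rose and the pdh2 gene LOC541705 fell. Of lists too small to test, rbcs1 rose and rca1 fell among C4 bundle sheath markers (0.53 and -0.64, 1 up and 3 down adjusted over the list alone), gols2 and rs2 rose in the raffinose and trehalose list, of which only gols2 fits by symbol (rs2 is a symbol of rough sheath2; 2 adjusted over the list alone), aba1 rose (2 adjusted over the list alone) and BIF1 was not called. Median, mean and test differed in sign for the pathogenesis-related, WRKY, NAC, LEA and cell cycle lists.

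Among the genes that fell by the naming rule, vignain fell by 5.41, AGA3a by 3.16, gln2 by 2.92 and LOB14 by 2.82 log2 units. Without TE insertion normal replicate 1 or 3 or drought replicate 1 the count was 2043, 2175 or 1933, and without the library labelled TE insertion drought replicate 2 it was 2763, of which 2508 were among the 3353. Of all genes, 35.4% had non-overlapping groups, where chance gives 10%, and other splits of the 6 libraries gave up to 3 passing lists against the 5 here.

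The interaction asks whether the drought response differs between the genotypes. CesA12 rose by 7.16 log2 units in ΔTE and 6.68 in TE insertion, bx1 by 1.94 and 2.51, and cab-m1 fell by 4.65 in ΔTE and by 3.36 in TE insertion. No gene passed for the difference in edgeR's quasi-likelihood test (1419 genes at an unadjusted p under 0.05, smallest adjusted p 0.316), against 68 with DESeq2 and 0 with limma-voom. No list passed, the smallest camera adjusted p being 0.0549 for root markers, and 0 list members were called over all genes. Adjusted over the list alone, 2 pathogenesis-related and chitinase members (pr6 and the peroxidase PRX42, which is also the 1 reactive oxygen member) and 1 shoot meristem member were higher and the dehydrin dhn2 lower. Median and mean differed in sign for the NAC and glutathione transferase lists, the photosystem test pointed down over a positive median and mean, the cell cycle test up over negative ones, and benzoxazinoid synthesis had a median of 0.16 with a mean of 0.0.

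Both drought responses shared 1204 genes that rose and 1259 that fell, where independent lists would share 150 and 156, and 2 genes were called in opposite directions. Across 24796 genes, which are not independent replicates, the log2 fold changes of the drought contrasts correlated at Pearson r = 0.611 and Spearman rho = 0.629 (jackknife SE of r 0.058), with a total least squares slope of TE insertion on ΔTE of 0.834 (jackknife SE 0.384). The genotype effects of both water regimes correlated at Pearson r = 0.162 and Spearman rho = 0.058 (jackknife SE of r 0.099). These jackknife SEs come from fits that each leave out 1 library and test a larger set of genes. Of the 29 genes called in normal water, 21 had the same sign under drought. The contrasts within each pair share no library. Without the library labelled TE insertion drought replicate 2, 118 of 133 had the same sign, and the interaction gave 0 genes, as with all libraries. The interaction count was 6 without ΔTE drought replicate 3, 2 without ΔTE normal replicate 2, and 1 without TE insertion normal replicate 2 or 3.

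**Figure D4:**
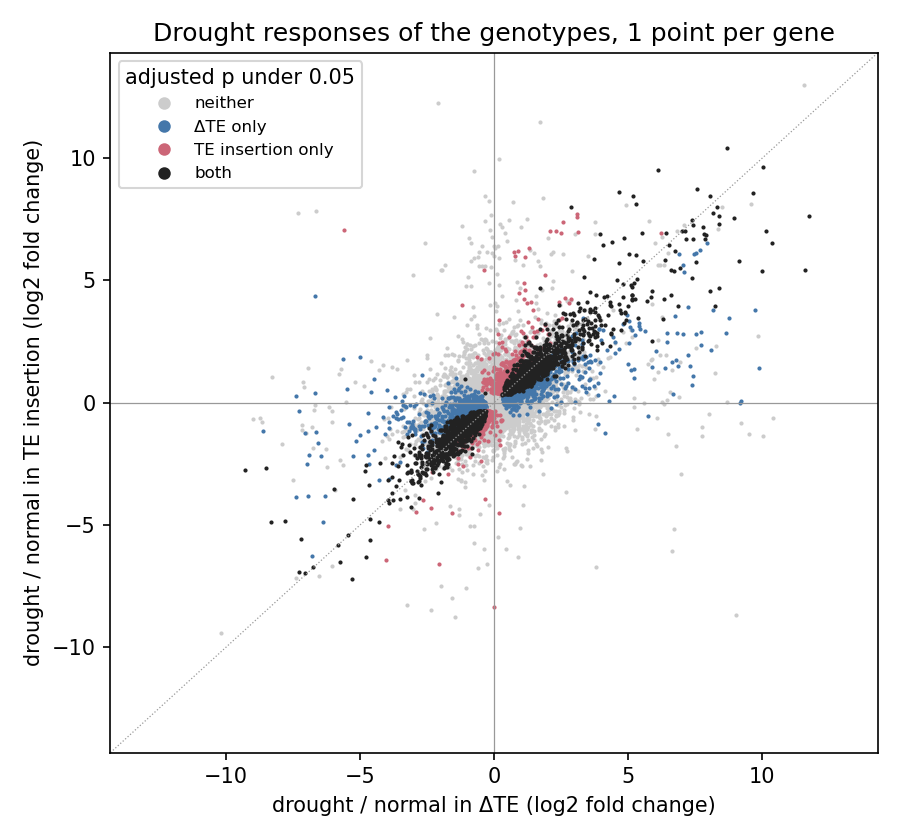
Log2 fold change of drought over normal water in TE insertion (vertical) against ΔTE (horizontal), 1 point per gene, coloured by whether the adjusted p was under 0.05 in neither, either or both genotypes. Pearson r is 0.611 over 24796 genes, and 2 genes were called in opposite directions.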

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

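The list tests without members of unrelated name, and every test of an explanation in this part, were chosen only after the results were seen.

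Pathogenesis-related and chitinase genes (6 members once unrelated names are left out) passed the test for a difference in drought response between the genotypes, with a median of -1.99 in ΔTE and 0.84 in TE insertion (camera adjusted p = 0.000212 for the interaction, 0.0876 with all fixed members, 0.257 with an estimated correlation, and 0.000275 without the library labelled TE insertion drought replicate 2). Root markers (8 members) passed likewise, with medians of -0.89 and -0.39 (camera adjusted p = 0.0219, 0.0549 with all fixed members, 0.421 with an estimated correlation, and 0.00415 without that library). Cytosolic ribosomal proteins (29 members) had medians of -0.11 and 0.08 (camera adjusted p = 0.0396, 0.0672 over the full set of lists, 0.727 with an estimated correlation, and 0.115 without that library). Of 23 lists these 3 passed for the interaction, and 29 of 100 splits of the libraries with the real one gave as many (8 in the highest other), so chance was not excluded. Lists in this form also passed for TE insertion under normal water, all towards lower values (jasmonate, camera adjusted p = 8.49e-05, pathogenesis-related, 0.0204, and benzoxazinoid, 0.047). Under drought others passed towards higher values in TE insertion (pathogenesis-related, camera adjusted p = 0.035, and ribosomal, 0.0377). The pathogenesis-related list thus changed direction between the water regimes. With all fixed members and an estimated correlation, the same lists did not pass in camera. In the same order, adjusted p was 0.774, 0.774 and 0.901 under normal water and 0.811 and 0.811 under drought. Groups of 3 libraries were not tested for outlying values.

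The library labelled TE insertion drought replicate 2 lay on the ΔTE side at 32 of the 33 genes that part the genotypes in normal water, as many as the ΔTE drought libraries. An exchange with a ΔTE drought library would need a partner out of place, and no ΔTE drought library was nearer TE insertion at more than 2 of these genes. A pool with seedlings of both genotypes would place many genes part of the way, and the upper quartile of the share of the way from ΔTE to TE insertion was 0.1. A ΔTE library under this label is a candidate explanation that these values leave open, and a wrong label with a library from outside the comparison stays open too. Over all 133 genes called between the genotypes in normal water by the fit without it, it was nearer ΔTE at 96. The ΔTE drought libraries were so at 92 to 99, and replicates 1 and 3 of its group at 20 and 17. Over the 29 genes called with all libraries, whose choice its spread entered, it was nearer ΔTE at 12. There the ΔTE drought libraries were so at 14 to 15, and replicates 1 and 3 of its group at 3 and 4. The label was left as deposited.

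Some genes that differ between the lines lay together on chromosome 3, which held 9 of the 28 placed calls. Of the 33 genes that part the genotypes in normal water, 9 lay there, 6 on chromosome 7 and others elsewhere. Without the library labelled TE insertion drought replicate 2, chromosome 3 held 46 of 128 placed normal water calls and 34 of 95 drought calls. It holds 10.76% of tested genes, and 28 of those normal water calls lay in 1 stretch of 150. Genotype effects of both regimes, multiplied as signed z scores, were averaged over 50 consecutive genes. The highest means lay on chromosome 3 (up to 2.54) and the next on chromosome 6 (1.11 and 0.78, against a mean of 0.087). Random placement of the calls did not give as dense a stretch in 10000 draws (one-sided permutation p = 1e-04, the smallest possible). A chance difference among the normal water libraries would not return under drought, yet 18 of the 95 placed drought calls made without the library labelled TE insertion drought replicate 2 fell in the same stretch, where 0.598 would by chance (one-sided Fisher's exact test, p = 6.26e-22). Of the 8 called genes there, 3 were higher and 5 lower in TE insertion, and 8 kept their sign under drought without that library. There 4 were called (LOC100275594, LOC100277712, LOC103649623 and LOC103649654, at -0.97, -1.54, 1.39 and 1.66 log2 units). The other 4 were not (edgeR adjusted p of at least 0.503). From normal water to drought LOC100283536 went from -1.74 to -0.1, LOC103651743 from 1.06 to 0.23, LOC100285293 from -1.39 to -0.42 and LOC110973014 from -1.1 to -0.67. A kept sign says little at the smallest of these sizes. With that library LOC100283536 went from -1.74 to 0.15. A linked segment that differs in sequence between the lines may account for this stretch, which leaves the calls on other chromosomes aside. An effect of ZmCCT on these genes was not tested and stays open, because each library of a line carries both.

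Photosystem genes were lower (as a list not called with an estimated correlation, adjusted p = 0.676 in ΔTE and 0.508 in TE insertion) and cellulose genes higher after drought, which fewer green cells per leaf could give. As the sole cause, that explanation needs photosystem genes and C4 mesophyll and bundle sheath markers to fall alike. The difference between these scores fell by 0.83 from normal to drought (6 libraries per condition, exact permutation within genotype over 400 splits, two-sided p = 0.005, the smallest possible). This test does not decide on fewer green cells, since the photosystem list was taken up because it fell in these same libraries. The mesophyll and bundle sheath scores also rest on only 6 and 4 genes. Of the 6 mesophyll members 5 fit by symbol, and in ΔTE pep4 rose while Ppdk1 fell. Photosystem scores fell by 1.1 (p = 0.005 by the same exact permutation), C4 mesophyll scores by 0.11 (p = 0.275) and bundle sheath scores by 0.45 (p = 0.02), with cell wall scores up by 2.33 (p = 0.005) and cell cycle scores by 0.17 (p = 0.055). Fewer green cells stay open as a cause of part or all of the photosystem fall, and bundle sheath scores fell too. A response to drought and a change with leaf age between the harvests stay open, untested, since the labels give water and harvest together.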

How the results depend on the processing

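The fits without both ΔTE libraries that lay apart, the lists without members of unrelated name, single libraries left out of the list tests and all settings for the slope were chosen only after seeing the data, and the rest were fixed before the data were examined. No named gene or list called in the main test or under an alternative changed sign there. Among those called in neither, named genes changed sign in 82 cases with single libraries left out and 29 under the other settings, and lists in 90 and 18. With DESeq2 the counts were 199 for TE insertion under normal water (29 in the main test), 119 under drought (1) and 68 for the interaction (0). With no filter they were 62 and 18 for the genotype comparisons, and with only the 2 groups in the fit 120 and 7. With only 2 groups in the fit, drought gave 3371 calls in ΔTE and 4229 in TE insertion, against 4519 and 3353 in the main test. Under drought limma-voom gave 7 and length-scaled TPM 8. A fold threshold of 1 log2 unit left 2143 and 1509 drought genes, by construction. Without both ΔTE libraries apart on the second component the counts were 3 for TE insertion under drought and 7 for the interaction. Except for the fold threshold, the cause was not tested.

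Leaving out single libraries gave 2 to 133 calls for TE insertion under normal water, 0 to 102 under drought, 3396 to 4556 for drought in ΔTE, 1933 to 3667 for drought in TE insertion and 0 to 6 for the interaction. The correlation of drought responses was 0.494 to 0.557, lower than the 0.611 with all libraries, and that of genotype effects 0.093 to 0.216. Each of these fits was filtered anew and tested more genes (24332 to 24428 with a chromosome, against 23817 with all libraries). The lower correlations can therefore not be laid to the library left out. The jackknife SEs are the spread of these fits around their own mean, not around the value with all libraries. The slope was 0.644 to 0.983, and the chromosome 10 share 0 to 16.7% (0 of 1 and 1 of 6 placed calls). Passing lists numbered 1 to 5 and 0 to 1 for the genotype comparisons, 5 to 8 and 5 to 7 for drought, and 0 to 5 for the interaction. With a filter of 1 CPM the correlation of drought responses was 0.673, and over called genes alone 0.834, with 0.583 for genotype effects.

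For the lists, an estimated correlation left 0 of 1 under normal water, 1 of 7 for drought in ΔTE and 1 of 5 for drought in TE insertion. In fry, 0 passed under normal water and 8 for drought in TE insertion. For drought in ΔTE the cell wall (fry adjusted p = 2.29e-06), benzoxazinoid (0.000825), phenylpropanoid (0.000825), lipid transfer (0.00259), ABA perception (0.00608) and root marker (0.0158) lists passed fry. There the photosystem list did not (0.0516), and the pathogenesis-related list did (0.00587), unlike in camera. Lists without unrelated names gave 3 and 2 passing lists for the genotype comparisons and 3 for the interaction. Upper-quartile scaling moved the drought calls to 2366 up and 2182 down in ΔTE and 1840 and 1503 in TE insertion, with median shifts of all genes of at most 0.048.

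The replicate numbers do not pair the libraries. Over 18 same-number pairs the correlation of deviations ran from -0.068 to 0.075, none over 0.1, and 5 of 12 libraries correlated best with their own number. With the replicate block the counts were 26, 6, 4398, 3228 and 0 in the order above, and 1 list passed for the interaction. Named genes called in the main test kept the call in 1785 cases with single libraries left out and lost it in 183, and under the other settings kept it in 1592 and lost it in 47. Named genes not called gained a call in 3 and 7 cases. ZmCCT has no values here, since its fixed names matched no gene. Simulated 1.5-fold changes were seldom recovered at these depths, spreads and group sizes, whose shares in this the simulation did not part.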

Other observations

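The tests of gene families by symbol stem and all tests on other splits of the samples were chosen only after the results were seen.

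Families of genes that share a symbol stem (85 with at least 5 tested members) were tested as well, and some of them share members with the fixed lists. With the preset correlation 9 passed for drought in ΔTE and 8 in TE insertion. Phosphate transporters (PHT) and ABA receptors (PYL) passed, as lower, in ΔTE and not in TE insertion (camera adjusted p = 0.0165 and 0.0376, against 0.254 and 0.502). The CEL stem passed, as higher, in TE insertion and not in ΔTE (0.0113, against 0.248), and benzoxazinoid genes (BX) passed in both. All these calls were lost with an estimated correlation (0.521 for PHT, 0.53 for PYL, 0.465 for CEL, and 0.521 and 0.559 for BX). The difference between the genotypes did not pass for PHT, PYL or CEL (camera adjusted p = 0.399, 0.399 and 0.468 for the interaction). Tubulins rose under drought, with 4 of 5 beta-tubulin genes called in each genotype (camera adjusted p = 0.00523 in ΔTE and 0.00543 in TE insertion, 0.521 and 0.465 with an estimated correlation). There tub6 rose by 5.32 and 5.05 and tub5 by 4.25 and 3.60 log2 units. Of alpha-tubulin genes 3 of 5 rose in each (camera adjusted p = 0.0134 and 0.00543, 0.635 and 0.764 with an estimated correlation), tua4 by 2.16 and 1.85. Cystatins, inhibitors of cysteine proteases, rose at 3 of 5 genes in each (camera adjusted p = 0.0191 and 0.0171, 0.521 and 0.559 with an estimated correlation), cc9 by 4.88 and 3.69.

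Of 23 protein phosphatase genes, mostly type 2C, 10 rose and 2 fell in ΔTE and 6 rose in TE insertion (camera adjusted p = 0.0222 and 0.0171, 0.521 and 0.559 with an estimated correlation). Some members of this class act with ABA receptors, and which of these genes do was not tested. PP2C14 rose by 3.64 and 3.07 and PP2C20 (LOC103636504) by 1.98 and 1.70 log2 units. Of 7 brittle stalk (COBRA-like) genes 5 rose and 2 fell in each genotype (camera adjusted p = 0.0466 and 0.0196, 0.521 and 0.488 with an estimated correlation), and Bk2L6 fell by 0.96 and 0.87. Cellulose synthases, 12 of 13 up in each, were the one family to pass with an estimated correlation (adjusted p = 0.0224 and 0.0156). No family passed for the genotype comparisons or the interaction. All genes named here were chosen after their values were seen.

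Other splits of the libraries ask how often a regrouping gives as large a result. Groups of 3 against 3 allow 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 29 and 3 genes for TE insertion under normal water, 1 and 4 under drought, 4519 and 2 for drought in ΔTE, and 3353 and 1 for drought in TE insertion. In the drought comparisons each other split mixes normal and drought libraries within its groups. The drought effect then enters the spread, so few calls in those splits follow from the design. For lists they were 1 and 6, 0 and 4, 7 and 6, and 5 and 3 in the same order. For the interaction, 100 splits were drawn, and chance was not excluded for the number of genes. Of these, 21 with the real one gave as many genes at an unadjusted p under 0.05 (1419 real, 2753 in the highest other). No fixed list passed in the real grouping (8 in the highest other), so a count of splits says nothing about these. The smaller drought response in TE insertion was an absolute log2 slope of 0.323 over called genes. It was reached by 6 of 100 splits with the real one (highest other 0.431), so chance was not excluded for it either. With only the 2 groups fitted, more genes were called in TE insertion (4229) than in ΔTE (3371), the reverse of the main test.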
